A study of Mus musculus with 6 samples.

How the data were processed

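Gene expression was measured by RNA sequencing of polyadenylated RNA in 6 libraries of a mouse dermal fibroblast cell line, 3 wild-type (WT) and 3 Lap2alpha knockout (KO). Cells were grown in DMEM with fetal calf serum, RNA was purified on columns, and stranded libraries were made with NEBNext kits and sequenced on a NextSeq 550, per the labels. The authors aligned the reads with STAR 2.7.10b to the mouse genome GRCm38 and deposited raw counts per Ensembl gene identifier, 1 file per library. The program that counted reads, its annotation release, its strand setting and its treatment of reads that match several places are not given in the sources used here. If the counting ignored strand, reads of overlapping genes on the opposite strand are included in a gene's count.

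The 6 files list the same 28293 genes in the same order, and each gene has at least 1 read in some library. The values are whole numbers that sum to a different total in each library, so they were used as counts with no further conversion. Symbols, positions, exonic lengths and GC content came from the GENCODE M21 annotation and the GRCm38 genome, in which 28230 of the identifiers were found and 63 were not. Levels are in CPM, each gene's count scaled to a library total of 1e+06, and are given as mean ± SD over the 3 libraries of a group. A count of 0 in all 3 libraries of a group was set to a floor of 3 counts over the group, and where a group held 1 to 3 counts the ratio is given with an exact 95% binomial (Clopper-Pearson) interval. Intervals and floors cover counting error only.

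KO was compared with WT in edgeR 4.0.16 under R 4.3.3, with TMM normalization, the default low-count filter (filterByExpr), a quasi-likelihood test for each gene and Benjamini-Hochberg adjustment. A gene is said to be called when its edgeR adjusted p was under 0.05, and fold changes are KO over WT. A total of 37 gene lists covered the nuclear lamina, the cell cycle, matrix, signalling, stress and metabolic pathways, chromatin and developmental regulators, markers of other cell types, RNA quality and sex. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Camera asks whether a list moved relative to the other genes. The fry test was run beside it and asks whether the members of a list moved, on balance, in 1 direction, without reference to other genes. Camera was also run on the tested genes of each chromosome, 21 sets in all. The share of called genes whose nearest tested neighbour was called in the same direction was compared with 10000 shuffles of the calls. Spearman correlations of the fold change with GC content, exonic length and gene density were computed across genes, which are not independent replicates.

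Genes are named by a rule with 4 parts: Tmpo; the 12 largest increases and the 12 largest decreases among called genes with at least 5 CPM in the higher group and no overlap between the KO and WT values, leaving out unnamed gene models and pseudogenes; up to 4 members of each list with the smallest p; and expressed members of the sex-linked list. The comparison, the tests, the lists and this rule were fixed before the data were examined. Genes named outside the rule were chosen after their values were seen, and this is said where they appear; Smchd1 was named for a test before its value was seen. Some genes that the rule names are not reported here.

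The tests were checked on simulated data made from these counts. In them 200 genes were changed and the others left unchanged. With 3 libraries a group, edgeR recovered 12.5% of genes changed 1.25-fold, 70.8% at 1.5-fold, 93.5% at 2-fold and 98.0% at 4-fold. Of its calls 9.03% were false. In the real data 11330 of 15081 tested genes were called, so these shares need not hold there. Camera found the simulated list that had been moved and called 0 of 20 unchanged lists. Genes were simulated independently of each other, so this check does not cover false list calls from correlation between genes. In the data the estimated correlation reached 0.81, for the mitochondrially encoded list. The alternatives tried were DESeq2 size factors, upper-quartile scaling, library totals alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, robust quasi-likelihood, the replicate number as a block, a GC-content offset, a 2-fold minimum and leaving out each library in turn. A test against a fold of 1.5, the subtraction of each chromosome's median and the omission of mitochondrially encoded genes were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The reads themselves were not used, so transcript isoforms were not quantified.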

Results

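The data are gene-level read counts from 6 RNA-seq libraries of a mouse dermal fibroblast cell line, 3 from wild-type cells (WT) and 3 from cells labelled as Lap2alpha knockout (KO). LAP2alpha is the isoform of lamina-associated polypeptide 2 that lacks a membrane anchor and binds A-type lamins in the nuclear interior. It is encoded by Tmpo, which also encodes the membrane-bound LAP2 isoforms. The WT libraries held 22159339, 26553616 and 24659885 counts and the KO libraries 27281473, 26519098 and 25768678 counts. Reads were found for 21067 to 21509 genes in the WT libraries and for 22273 to 22637 genes in the KO libraries. The Pearson correlation of log2 CPM was 0.993 to 0.996 within groups and 0.912 to 0.918 between groups, and the first principal component, which separated KO from WT, held 91.2% of the variance. Mitochondrially encoded genes took 4.13 ± 0.351% of the counts in KO and 2.15 ± 0.268% in WT (mean ± SD, n = 3 libraries). The 10 most abundant genes took 6.38 ± 0.0539% in KO and 4.97 ± 0.163% in WT. The labels do not say whether replicates were separate cultures or clones, so the p-values measure only the spread between these libraries. Differences between lines or clones cannot be separated here from the loss of LAP2alpha.

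The comparison asks which genes differ in expression between the cells labelled KO and WT, in a study whose title concerns chromatin organization and the position of A-type lamins. Most measured genes differed. Genes of DNA replication, mitosis, the HMG chromatin proteins and the unfolded protein response were mostly lower in KO, and genes of the Wnt pathway, the protocadherin clusters, interferon response, collagens and fibroblast identity were mostly higher, though 7 of 36 matrix genes and 5 of 31 interferon genes fell. Camera called these lists with a preset correlation, and none held with an estimated correlation (camera adjusted p = 0.071 to 0.466). For the Wnt list the estimated correlation (−0.012) was under the preset 0.01, so a higher correlation between genes does not account for its loss. The mitosis list's estimated correlation (0.011) was close to the preset, so the same holds there. Tmpo itself fell to 129 ± 6.81 CPM in KO from 252 ± 2.65 CPM in WT (n = 3), a 2.05-fold decrease with a log2 fold change of −1.04 (SE 0.0549, edgeR adjusted p = 4.9e-08). Tmpo (ENSMUSG00000019961) lies on chromosome 10 at 91147571 to 91181315 on the minus strand of GRCm38, and the annotation gives it 13 transcripts, 5 of them protein-coding. Its count sums reads of all LAP2 isoforms, so the level of the alpha isoform was not measured on its own.

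Of 15081 tested genes, 11330 (75.1%) were called in edgeR, 5678 of them higher and 5652 lower in KO. This balance depends on the scaling, with 6181 higher and 5139 lower under library totals alone. The median absolute log2 fold change of the called genes was 0.78. At least 2-fold changes were called for 4233 genes, of which 2518 were higher and 1715 lower. At least 4-fold changes were called for 1296 genes, of which 987 were higher and 309 lower, so the larger changes were mostly increases. The KO and WT values did not overlap for 11589 tested genes (76.8%), where chance gives 10%. Among protein-coding genes, 9588 of 12119 were called.

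**Figure D1:**
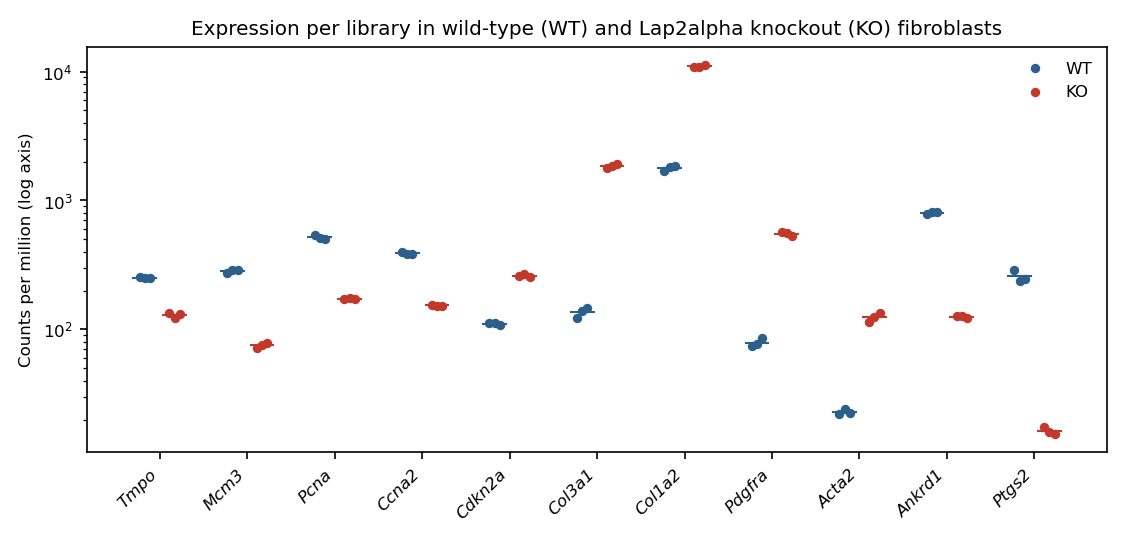
CPM in each library (log axis) for Tmpo and 10 other genes named in the text. Each point is 1 library and each bar a group mean, WT in blue and KO in red, and Tmpo stood at 129 CPM in KO and 252 CPM in WT.

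The largest increases were in genes that were nearly silent in WT. Tnr, which encodes tenascin-R, stood at 30.3 ± 1.85 CPM in KO and 0.0512 ± 0.0572 CPM in WT (n = 3), a log2 fold change of 8.92 (SE 0.229, edgeR adjusted p = 5.4e-10), and at 10.11 when WT replicate 2 was left out. Aldh3a1, an aldehyde dehydrogenase, rose 256-fold to 41.7 ± 0.475 CPM, and Col11a1, a chain of a cartilage collagen, rose 170-fold to 76.5 ± 1.04 CPM. Crocc2, a ciliary rootlet gene, rose to 31.5 ± 2.14 CPM with a log2 fold change of 7.87 (8.47 without WT replicate 1). The other 8 of these 12 genes had only 1 to 3 counts over the WT group. Among them, Col6a5, a collagen VI chain, was 479-fold higher in KO (95% counting interval 132 to 3961), Ednra, the endothelin A receptor, was 286-fold higher (78.9 to 2369), and Hkdc1, a hexokinase family member, was 170-fold higher (57.8 to 825). All WT counts of Ggt5, Wnt4 and Sparcl1 came from WT replicate 1, and their ratios were 518 (92.6 to 20505), 385 (106 to 3184) and 223 (61.4 to 1848). The ratio was 168 (57.2 to 818) for Mpped2, whose log2 fold change was 7.16 and 8.06 without WT replicate 1, and 164 (56.0 to 800) for Acss3, where 33.9% of the exonic sequence overlaps Ppfia2 on the opposite strand.

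The largest decrease was in Gria3, which was not detected in KO. Gria3, a glutamate receptor subunit on the X chromosome, had 25.04 ± 1.21 CPM in WT and 0 counts in all 3 KO libraries, at least 664-fold lower with the floor of 3 counts taken over the group. Sulf1, which removes sulfate groups from heparan sulfate, fell 27.8-fold from 246 ± 5.84 to 9.33 ± 0.471 CPM (n = 3; log2 fold change −4.80, SE 0.0621, edgeR adjusted p = 3.9e-11). Hpse, which encodes heparanase, also fell (log2 fold change −4.14). Slc1a3, a glutamate transporter, fell from 31.2 ± 0.747 to 0.728 ± 0.0687 CPM. Cxadr, an adhesion protein and virus receptor, fell from 14.6 ± 2.67 to 0.0614 ± 0.0761 CPM, with a log2 fold change of −7.82 (−9.30 without KO replicate 1). Eid2 had 3 counts in KO and was 218-fold lower (counting interval 74.2 to 1060), and its log2 fold change of −7.66 was −8.49 without KO replicate 2. The remaining decreases were Tro (−6.43), Smoc1 (−5.76), Tmeff1 (−5.58), Cyp3a13 (−4.87), Rhox5 (−4.38) and Plac9b (−4.24), the last of which has a near-identical neighbour, Plac9a.

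Cell cycle genes were lower in KO. All 38 tested members of the DNA replication and E2F target list fell, with a median log2 fold change of −1.25. Rrm2, a subunit of ribonucleotide reductase, fell from 216 ± 6.66 to 54.8 ± 0.882 CPM (n = 3; log2 fold change −2.05, SE 0.0524, edgeR adjusted p = 5.2e-10), and Mcm3, part of the replicative helicase, from 284 ± 7.36 to 75.4 ± 3.10 CPM. Pcna, the sliding clamp of DNA polymerases, fell from 518 ± 16.7 to 173 ± 2.31 CPM. In the G2/M and mitosis list 30 of 32 members fell, with a median of −1.08, among them the cyclin Ccna2 (−1.42), the spindle motor Kif11 (−1.79) and Birc5 (−1.29). The exceptions, chosen after their values were seen, were Cenpe, which rose (0.16), and the proliferation marker Mki67, which was not called at 213 ± 3.98 CPM in KO and 201 ± 18.1 CPM in WT (0.01). Camera called both lists, with an adjusted p of 1.1e-12 for replication and 5.6e-09 for mitosis. With an estimated correlation the camera adjusted p = 0.071 for both lists, so neither call held. For mitosis the estimated correlation (0.011) was close to the preset 0.01, so its lost call is not a sign of correlated genes. The replication list's estimated correlation was higher (0.059).

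Of 9 tested HMG genes, which encode architectural chromatin proteins, 8 fell and 1 rose, with a median log2 fold change of −0.94. Hmga2 fell from 476 ± 31.2 to 99.2 ± 9.67 CPM (n = 3), Hmgb3 from 142 ± 4.69 to 52.1 ± 1.09 CPM, Hmgb2 by a log2 fold change of −1.44 and Hmga1 by −1.46, while Hmgn3, chosen after its value was seen, rose (0.54). Camera called this list (adjusted p = 0.0062), but the camera adjusted p = 0.283 with an estimated correlation. Replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail that these libraries select for, went both ways, with 13 higher, 21 lower and 17 not called (median −0.42, or −1.05 for members with at least 1 CPM; camera adjusted p = 0.374). Hist1h1c rose from 14.98 ± 1.21 to 84.7 ± 0.853 CPM and Hist1h2bc rose (1.72), whereas Hist1h2ap and Hist1h2ao, which are near-identical in sequence and share reads, fell by the same amount (−1.73). The Rb pathway and CDK inhibitor list had 7 members higher, 9 lower and Rb1 not called (0.19), with a median of −0.34 and a mean of 0.01 (camera adjusted p = 0.785). Cdkn2a and Cdkn2b, neighbouring genes for the inhibitors p16/p19 and p15, rose (1.16 and 1.46), and the cyclin Ccnd1 (−1.21) and E2f4 (−1.37) fell. Of the p53 targets 10 rose and 8 fell, while Sesn2 (−0.20) and Bbc3 (0.08) were not called. Sesn1 (1.99), Trp53inp1 (4.33) and Eda2r (2.19) rose and Aen (−1.77) fell, and the list's median (0.15) and mean (−0.01) differ in sign, as do camera (up, adjusted p = 0.879) and fry (down). Rb1, Sesn2 and Bbc3 were chosen after their values were seen.

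Matrix and fibroblast marker genes rose. In the list of collagens and matrix proteins 23 of 36 tested members were higher, 7 lower and 6 not called, with a median log2 fold change of 0.90 (camera adjusted p = 0.0014). That call was lost with an estimated correlation (camera adjusted p = 0.466). Col1a2, a chain of type I collagen, rose from 1788 ± 80.1 to 10955 ± 184 CPM (n = 3), and Col3a1, type III collagen, rose from 136 ± 11.5 to 1852 ± 57.8 CPM, a log2 fold change of 3.69 (SE 0.0709, edgeR adjusted p = 1.4e-10). Lama4, a laminin chain, rose 28.1-fold and Col5a3 rose 13.3-fold. Of 14 fibroblast identity genes 13 rose, with a median of 1.10, or 0.66 for members with at least 1 CPM (camera adjusted p = 0.0011; camera adjusted p = 0.244 with an estimated correlation). Dpt, which encodes dermatopontin, rose from 6.81 ± 0.531 to 195 ± 6.18 CPM, the growth factor receptor gene Pdgfra from 79.1 ± 5.92 to 553 ± 17.0 CPM and Pdgfrb from 47.6 ± 6.13 to 246 ± 9.62 CPM, and Ly6a also rose (1.56). Thy1, a common fibroblast surface marker chosen after its value was seen, fell (−0.75).

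Among matrix remodelling enzymes and inhibitors 17 rose and 10 fell. Loxl2, a lysyl oxidase that cross-links collagen, rose 41.7-fold to 118 ± 2.18 CPM (n = 3) while its relative Loxl4 fell from 70.4 ± 4.06 to 6.99 ± 0.313 CPM. Adamts2, a procollagen peptidase, rose (2.56). The list's median was 1.18 and its camera adjusted p = 0.061. Of 16 contractile and myofibroblast genes 10 rose, among them Acta2, smooth muscle actin (22.9 ± 1.13 to 125 ± 9.93 CPM), Myl9 (3.46), Mylk (2.09) and Itga8 (5.84). Cnn2 fell (−0.48), and Cnn1 (0.34), Synpo2 (−0.54), Tpm1 (−0.06), Cald1 (−0.03) and Myocd (0.11) were not called; these 6 were chosen after their values were seen. Camera called this list (median 0.42, adjusted p = 0.033), and the camera adjusted p = 0.361 with an estimated correlation. Of 11 chondrocyte and osteoblast markers 9 rose, with Col11a1 given above, Matn2 (2.46) and Sox5 (2.88) as examples, and Spp1, osteopontin, fell from 1295 ± 45.9 to 281 ± 9.82 CPM. The remaining member, Col11a2, chosen after its value was seen, was not called (0.47). This list had a median of 2.46 (camera adjusted p = 0.0062), with a camera adjusted p = 0.224 with an estimated correlation.

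TGF-beta and BMP pathway genes went both ways, with 16 higher and 7 lower (median 0.62, camera adjusted p = 0.127). Tgfbi, a matrix protein induced by TGF-beta, rose from 7.19 ± 0.668 to 245 ± 7.56 CPM (n = 3), the BMP antagonist Grem1 rose (1.74), and of the latent TGF-beta binding proteins Ltbp2 rose (2.00) and Ltbp1 fell (−1.59). Bambi (0.16) and Id2 (−0.06) were among those not called. Of the YAP/TEAD targets 7 rose and 10 fell (median −0.31, camera adjusted p = 0.260). The 4 targets with the smallest p fell: Ankrd1 from 801 ± 14.5 to 125 ± 2.76 CPM, and Ccn2, connective tissue growth factor, from 117 ± 3.94 to 19.9 ± 1.27 CPM, with Nuak2 (−1.73) and Wwc1 (−1.27) lower too, while Nt5e (2.12) and Tgfb2 (1.83) rose. The annotation places 23.2% of the exonic sequence of Ccn2 opposite a gene model on the other strand. Fjx1 (−0.27), Ptpn14 (−0.14) and Lats2 (−0.16) were not called. Nt5e, Tgfb2 and the genes named here that were not called were chosen after their values were seen.

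Wnt pathway genes rose together. Of 22 tested members, which include ligands, receptors, secreted inhibitors and transcription factors, 20 rose and 2 were not called, with a median log2 fold change of 1.65. Sfrp2, a secreted Wnt modulator, rose from 179 ± 7.99 to 535 ± 23.3 CPM (n = 3; log2 fold change 1.51, SE 0.0569, edgeR adjusted p = 5.2e-09). The receptors Ror1 and Ror2 rose from 0.162 ± 0.0265 and 0.0813 ± 0.0370 CPM to 8.57 ± 0.743 and 7.06 ± 0.435 CPM, and Wnt4 is among the largest increases above. Wnt9a (−0.45) and Tcf7l2 (−0.02), chosen after their values were seen, are the members that were not called. Camera called the list (adjusted p = 2.6e-06), and the camera adjusted p = 0.071 with an estimated correlation.

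Interferon-stimulated genes were mostly higher, with 24 of 31 rising, 5 falling and 2 not called. Gbp2 and Gbp3, interferon-induced GTPases, rose from 1.23 ± 0.214 and 0.668 ± 0.227 CPM to 27.1 ± 1.12 and 11.9 ± 0.512 CPM (n = 3), and Ddx58, the RNA sensor RIG-I, rose (1.71). The members that fell were Ifit3 (−1.14), Ifit2 (−1.17), Ifit3b (−0.70) and Ifit1 (−0.64), which are neighbours on chromosome 19, and Cxcl10 (−1.05). Xaf1 (−0.22) and Oasl1 (−0.06) were not called, and apart from Ifit3 these exceptions were chosen after their values were seen. The list's median was 1.27 (camera adjusted p = 0.0014), and the camera adjusted p = 0.361 with an estimated correlation. Of 20 chemokines and inflammatory mediators 13 rose and 7 fell (median 1.20, camera adjusted p = 0.127). The chemokine gene Cxcl12 rose from 204 ± 5.91 to 1567 ± 133 CPM, Ccl9 (3.81) and complement C3 (3.71) rose, and Ptgs2, cyclooxygenase-2, fell from 259 ± 28.0 to 16.3 ± 1.06 CPM. Immediate early genes, which respond to serum and growth factors, were mostly lower, with 7 higher, 18 lower and a median of −0.47. Ier3 fell from 135 ± 0.780 to 24.9 ± 1.60 CPM, Nr4a1 (−3.08), Ier5 (−1.48) and Myc (−1.22) fell, and Jund (−0.18), Fosl2 (0.10), Junb (0.17), Fos (0.20) and Fosb (−0.09), chosen after their values were seen, were not called. Camera called this list (adjusted p = 0.034), and the camera adjusted p = 0.244 with an estimated correlation and 0.054 with a filter of at least 1 CPM.

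Genes of the unfolded protein response and amino acid stress list were mostly lower, with 17 falling and 4 rising of 23 (median −0.61, camera adjusted p = 0.0025). With an estimated correlation the camera adjusted p = 0.283. The chaperone gene Calr fell from 1986 ± 38.8 to 926 ± 33.8 CPM (n = 3), and Manf (−1.53), Pdia6 (−1.09) and Psat1, a serine synthesis enzyme (−1.38), fell. Dnajc3 (0.67), Asns (0.44), Xbp1 (0.30) and Edem1 (0.25) rose, and Sel1l (−0.09) and Herpud1 (−0.04) were not called. Of 28 glycolysis and hypoxia genes 16 fell and 6 rose (median −0.27, camera adjusted p = 0.076). The glycolytic enzyme genes Pgam1 (959 ± 8.31 to 288 ± 3.71 CPM), Pgk1 (1611 ± 43.2 to 698 ± 23.3 CPM), Ldha (−1.08) and Hk2 (−1.10) fell. Of 22 cholesterol synthesis genes 12 rose and 4 fell (median 0.21, camera adjusted p = 0.144), with Nsdhl (0.72), Tm7sf2 (1.17), Dhcr7 (0.91) and Srebf2 (0.48) higher, and Msmo1 (−0.50), Sc5d (−0.31) and Lss (−0.13) among the lower genes. NRF2 and glutathione genes had 8 higher, 5 lower and 7 not called (median 0.03, and −0.01 without WT replicate 1; camera adjusted p = 0.429). The glutathione transferase genes Gsta4 (2.23), Gstm1 (2.37) and Gstm2 (1.72), the last 2 of which are similar in sequence, rose, and Gclc (−1.12), Gsr (−0.98), Txnrd1 (−0.83), Prdx1 (−0.62) and Taldo1 (−0.50) fell. The exceptions from Dnajc3 to Herpud1, the lower cholesterol genes named, and Gsr, Txnrd1, Prdx1 and Taldo1 were chosen after their values were seen.

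Genes of the nuclear lamina and envelope changed modestly, with 14 lower, 5 higher and 4 not called of 23 (median −0.28, camera adjusted p = 0.076). Sun2 and Syne3, parts of the bridge between nucleus and cytoskeleton, rose by log2 fold changes of 0.74 and 0.85, and the nucleoporin gene Nup153 fell (−0.83). Lmna, which encodes the A-type lamins named in the study's title, stood at 641 ± 65.8 CPM in KO and 483 ± 24.5 CPM in WT (n = 3; log2 fold change 0.33, SE 0.0763, edgeR adjusted p = 0.0024). The B-type lamin genes Lmnb1 (−0.27) and Lmnb2 (−1.15) and the lamin B receptor gene Lbr (−0.89) fell. Syne1 (0.33) and Syne2 (0.26) rose, and Lemd3 (−0.06), Tor1aip1 (0.03), Lemd2 (0.04) and Tor1aip2 (0.02) were not called. The lamin genes, Lbr and these 6 were chosen after their values were seen. Of 40 chromatin modifiers 19 rose, 11 fell and 10 were not called (median 0.18, camera adjusted p = 0.331). The demethylase genes Kdm5b (2.42), Kdm6b (1.54) and Tet2 (2.52) rose and the Polycomb gene Eed fell (−1.10).

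The clustered protocadherins, neuronal adhesion genes in tandem arrays on chromosome 18, rose as a group in the beta and gamma clusters. Of 43 clustered genes with a read, 23 were tested, none of them from the alpha cluster. Of 23 tested members 22 rose and 1 was not called, with a median log2 fold change of 2.46 (camera adjusted p = 5.5e-07). With an estimated correlation the camera adjusted p = 0.071. In the beta cluster (37294812 to 37524479) all 12 tested genes rose, with a median of 3.06, and the summed level was 128 CPM in KO and 16.0 CPM in WT. In the gamma cluster (37661793 to 37841873) 10 of 11 tested genes rose, with a median of 1.56 and sums of 212 and 91.6 CPM. Most of these sums came from Pcdhgc3, chosen after its value was seen, at 186 CPM in KO and 84.0 CPM in WT (1.07). Pcdhb18 rose from 0.762 ± 0.0452 to 14.8 ± 1.89 CPM (n = 3) and Pcdhb22 from 4.85 ± 0.727 to 33.7 ± 2.20 CPM, with Pcdhb5 (3.20) and Pcdhb17 (2.46) also higher. The gene that was not called, Pcdhga11, was chosen after its value was seen (0.46). The only alpha gene with a read, Pcdha12, was near 0 in both groups (0.0248 CPM in KO, 0.0411 CPM in WT). Pcdha12 was also chosen after its value was seen. The gamma genes share constant 3′ exons, so reads there cannot be assigned to a single member, and the beta genes do not share such exons.

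**Figure D2:**
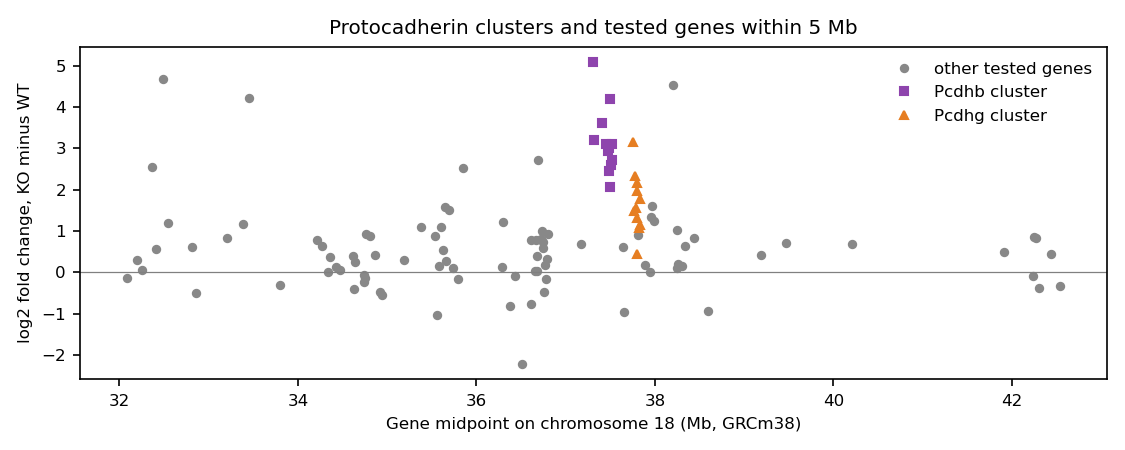
Log2 fold change, KO over WT, of each tested protocadherin gene against its position on chromosome 18 (Mb), with beta members as squares, gamma members as triangles and other tested genes within 5 Mb as grey points. All 12 beta members lie above 0, and their median is 3.06.

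The list of Hox genes, which mark position along the body, went both ways, with 7 members higher, 11 lower and 10 not called (median −0.14, camera adjusted p = 0.420). It was matched by symbol and also holds antisense RNAs. Of these Hoxd3os1 (0.67) is among the higher members, and Hoxaas2, Hoxaas3 and Hoxb3os are among those not called. Hoxc6 rose from 34.8 ± 0.822 to 81.9 ± 4.12 CPM (n = 3) and Hoxc8 rose (1.05), while Hoxd8 fell (−1.14) and Hoxa10 fell from 1.82 ± 0.0615 to 0.0754 ± 0.0653 CPM (−4.58, and −5.49 without KO replicate 2). Of 21 positional and dermal transcription factors 14 rose and 5 fell, with Meis1 (1.84) and Gata6 (1.17) higher, and Foxc2 (−0.98), Twist2 (−0.54), Lhx9 (−1.18), Twist1 (−0.29) and Irx5 (−0.20) lower. Emx2 (−0.03) was among those not called. The list's median was 0.58 and its camera adjusted p = 0.061, and camera called it without KO replicate 2 or KO replicate 3 (adjusted p = 0.049 for both). Of 15 imprinted genes 8 rose and 5 fell (median 0.45, camera adjusted p = 0.429). Dcn, the proteoglycan decorin, rose from 26.8 ± 2.56 to 309 ± 37.5 CPM and Sgce rose (1.60). Peg12 (−2.08), Mkrn3 (−1.03), Snrpn (−0.64) and Ube3a (−0.26), which lie in the Prader-Willi and Angelman region, fell, as did Grb10 (−0.81). Zrsr1 (0.48) and Kcnq1ot1 (−0.03) were not called. Of the genes in this paragraph the antisense RNAs of the Hox list, Twist2, Lhx9, Twist1, Irx5, Emx2, Mkrn3, Snrpn, Ube3a, Zrsr1 and Kcnq1ot1 were chosen after their values were seen.

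Of 8 lists of markers of other cell types 5 had a positive median and 3 a negative one, and camera called only the chondrocyte and osteoblast list given above. Of 10 neuronal markers 6 rose and 2 fell (median 1.28, camera adjusted p = 0.136; median 0.36 for members with at least 1 CPM): Nefm, a neurofilament gene, rose from 1.03 ± 0.190 to 27.4 ± 1.99 CPM (n = 3), Syt1 rose (1.93), and Gap43 (36.6 ± 1.88 to 3.38 ± 0.129 CPM) and Map2 (−1.08) fell. Ncam1 (0.06) and L1cam (−0.03) were not called. Of 5 melanocyte and Schwann cell markers Pmp22, a myelin protein gene that fibroblasts also express, rose from 48.6 ± 2.52 to 228 ± 2.25 CPM, Mbp (2.01) and Mitf (1.39) rose, and Dct fell (−1.49; median 1.89, camera adjusted p = 0.069, and 0.049 without KO replicate 3). Of 5 endothelial and pericyte markers Notch3 rose from 7.24 ± 1.17 to 41.1 ± 2.18 CPM, Rgs5 was 127-fold higher (22.5 to 5062) on 1 WT count, which came from WT replicate 3, Flt1 (−2.76) and Cdh5 (−2.44) fell, and Egfl7 was not called (0.30; median 0.30, camera adjusted p = 0.755). Of 5 leukocyte markers Csf1r (3.35), Coro1a (2.02), Cd74 (3.29) and Cd14 (0.80) rose, and Cd68 was not called (0.42; median 2.02, camera adjusted p = 0.066). Camera called this list without WT replicate 1 (adjusted p = 0.045), WT replicate 3 or KO replicate 1 (adjusted p = 0.049 for both). Ncam1, L1cam, Dct, Egfl7 and Cd68 were chosen after their values were seen.

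Of 8 adipocyte markers Fabp4 (−1.71), Pparg (−3.26), Dgat2 (−0.84) and Cfd (−2.13) fell, Cebpa (3.90) and Plin4 (0.82) rose, and Scd1 (−0.08) and Lpl (0.05) were not called (median −0.46, camera adjusted p = 0.399). Of 6 skeletal muscle markers Tnnt3 rose from 0.923 ± 0.122 to 9.48 ± 0.135 CPM (n = 3), Chrna1 fell (−1.07), and Tnnt2 (−0.82), Mylpf (−0.31), Myl4 (−0.20) and Tnnc1 (−0.08) were not called. This list's median was −0.26, its mean 0.13, camera's direction down (adjusted p = 0.812) and fry's up. Chrna1 was not called without WT replicate 1 (edgeR adjusted p = 0.085, log2 fold change −0.65) or KO replicate 3 (edgeR adjusted p = 0.058). Only 4 keratinocyte markers were tested, too few for the list test, and Krt7 (−2.62), Cdh1 (−0.97) and Krt10 (−0.54) fell and Sfn (0.69) rose. Sfn was not called without WT replicate 2, WT replicate 3 or KO replicate 3 (edgeR adjusted p = 0.057, 0.083 and 0.062), nor Krt10 without KO replicate 2 (edgeR adjusted p = 0.070). Of the sex-linked list only Xist and Tsix are among the genes with a read in some library. The Y-linked members Ddx3y, Eif2s3y, Kdm5d and Uty are absent. Only Xist, the RNA that coats the inactive X chromosome, was tested. Xist stood at 844 ± 93.5 CPM in KO and 898 ± 87.5 CPM in WT and was not called (log2 fold change −0.17, edgeR adjusted p = 0.11). The edgeR adjusted p of Xist was 0.0058 with no low-count filter, 0.037 without WT replicate 2 and 0.026 without KO replicate 1. Cfd, Plin4, Scd1, Lpl, Tnnt2, Mylpf, Myl4, Tnnc1, Tsix and the absent Y-linked genes were chosen after their values were seen.

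Mitochondrially encoded genes rose along with their share of the counts given above: 20 of 27 rose and 7 were not called, with a median log2 fold change of 0.88 (camera adjusted p = 0.0025). The camera adjusted p = 0.626 with an estimated correlation. mt-Co1, a cytochrome oxidase subunit, rose from 4107 ± 343 to 8461 ± 633 CPM (n = 3), mt-Cytb from 1503 ± 112 to 3435 ± 113 CPM, and mt-Nd5 (1.45) and mt-Nd4l (1.30) rose. Cytosolic ribosomal protein genes were slightly lower, with 45 falling, 6 rising and 27 not called of 78 (median −0.20, camera adjusted p = 0.0020). The camera adjusted p = 0.617 with an estimated correlation. Rpl7 fell from 1283 ± 15.1 to 765 ± 9.03 CPM, Rpl15 from 1634 ± 37.5 to 1142 ± 17.1 CPM, and Rps27l by −0.91. These genes, like Pgam1 and Hmga1, have processed pseudogenes with which short reads can be shared.

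Of the 35 lists tested, camera called 14, 8 of them up and 6 down, and 20 had an unadjusted p under 0.05. With an estimated correlation it called 0 lists, 7 had an unadjusted p under 0.05, and fry called 33. Adjusted over the list alone, the counts of higher and lower members were the same as those over all genes in 35 of 37 lists; the others were the p53 targets, with 9 rather than 8 lower, and the ribosomal proteins, with 5 rather than 6 higher. The KO and WT values of Krt10 and of Xist overlapped. Ddit4l, a p53 target, had 0 counts in all KO libraries, and Meox1 and Gria1, of the positional and neuronal lists, had 0 counts in all WT libraries. With these genes, chosen after their values were seen, at their bounds, the list medians stayed at 0.15, 0.58 and 1.28. Under 3 other scalings, which move all genes by nearly the same amount, list medians shifted by at most 0.08, and with a GC-content offset by at most 0.17; no median changed sign.

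**Figure D3:**
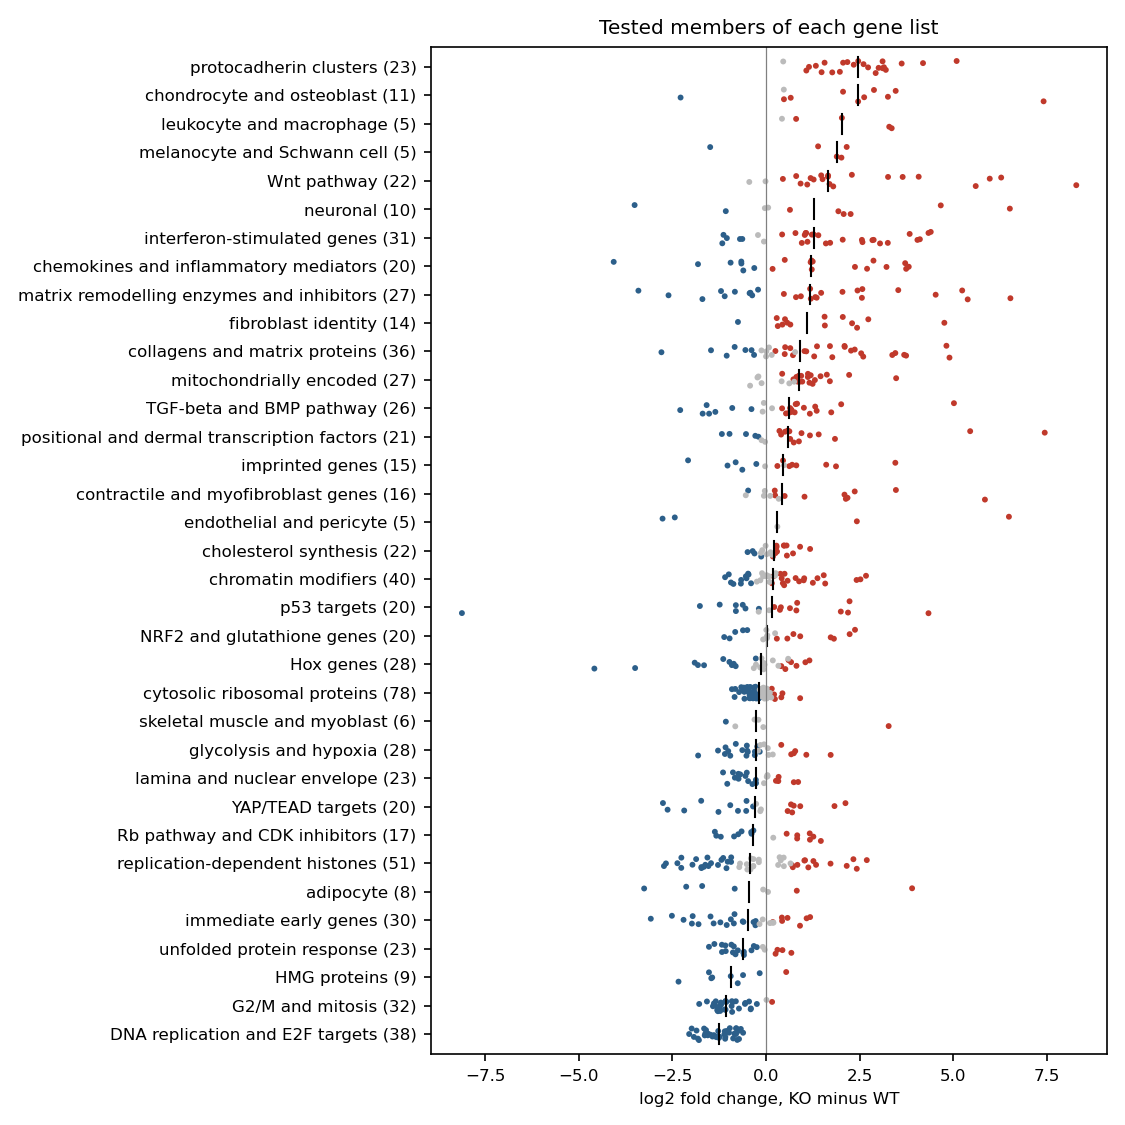
Log2 fold change, KO over WT, of the tested members of each gene list (1 point per gene; red called higher, blue called lower, grey not called), with a bar at the list's median and the number of tested members in brackets. The replication list lies wholly below 0, with a median of −1.25, and the protocadherin list has a median of 2.46.

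Expression also differed by chromosome. Chromosome 19 was lower: 304 of its 517 tested genes (58.8%) fell and 96 rose, with a median log2 fold change of −0.48 (camera adjusted p = 1.4e-05). Chromosome 18 was higher, with 237 genes rising and 82 falling of 412 (median 0.43, camera adjusted p = 2.3e-04), and so was chromosome 15, with 316 rising and 153 falling of 615 (median 0.31, camera adjusted p = 0.011). With an estimated correlation the camera adjusted p = 0.226, 0.226 and 0.240 for chromosomes 19, 18 and 15; 0 of the 21 sets were then called in camera, and 4 had an unadjusted p under 0.05. The medians of the other chromosomes lay between −0.19 for the 5 tested genes of the Y chromosome and 0.25 for chromosome 6. These Y genes do not include Ddx3y, Eif2s3y, Kdm5d or Uty, which are absent from the counts. On chromosome 19 the 10-Mb windows with at least 20 tested genes had medians from −1.01 (30 to 40 Mb) to −0.18.

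**Figure D4:**
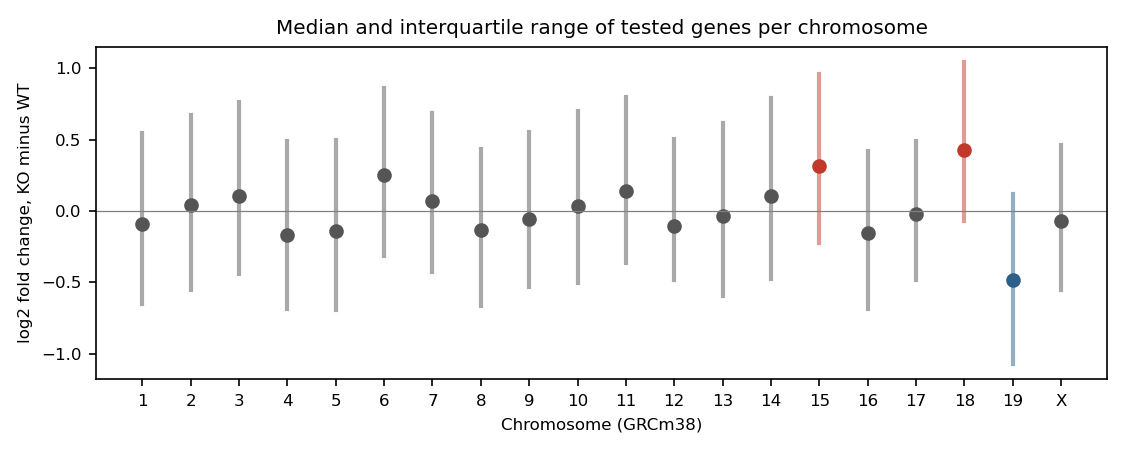
Median log2 fold change, KO over WT, of the tested genes of each autosome and the X chromosome (points), with bars from the lower to the upper quartile; sets called higher are red and those called lower blue. Chromosome 19 has the lowest median (−0.48) and chromosome 18 the highest (0.43).

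Called genes lay next to genes called in the same direction more often than in shuffled calls. The share was 45.7%, against a mean of 37.6% and a maximum of 39.5% in 10000 shuffles (permutation p = 1e-04, the smallest these shuffles can give, one-sided). For called genes of at least 2-fold it was 26.6% against a mean of 14.5%, and with tandem gene families left out it was 45.1%. The calls were shuffled across all chromosomes, so the shifts of whole chromosomes given above can add to the excess. The share was not recomputed within chromosomes, and reads shared by overlapping neighbours were not taken out. Across 15068 genes, which are not independent replicates, the fold change had a Spearman correlation of 0.092 with GC content, 0.098 with exonic length and 0.043 with gene density.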

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

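The test against a fold of 1.5, the subtraction of chromosome medians and the omission of mitochondrial genes were chosen after seeing the data. A 2-fold minimum left 4233 of the 11330 called genes (2518 higher, 1715 lower), and the test against a fold of 1.5 left 5621 (3094 higher, 2527 lower); a minimum size leaves fewer genes by construction. Leaving out 1 library gave 10791 (without KO replicate 2) to 11441 genes (without WT replicate 1), 5352 to 5678 higher and 5327 to 5775 lower. Of the other settings the lowest count was 10514 of 13482 tested genes with at least 1 CPM, and the highest 12588 of 28293 with no filter, with fewer and more genes tested. Under library totals alone 54.6% of the called genes were higher, against 50.1%, with a median over all genes of 0.09 against 0.01. The fold change of Tmpo stayed between −0.96 and −1.06. Camera called 14 lists and 3 chromosomes with the preset correlation and 0 of each with an estimated correlation. Fry called 33 lists, and camera called 14 to 16 without 1 library. The lost Wnt (−0.012), chondrocyte and osteoblast (−0.0035) and immediate early (−0.00028) lists had estimated correlations under the preset 0.01. The unadjusted camera p of the Wnt list still rose from 3.0e-07 to 0.0049. For the mitosis list the estimated correlation (0.011) was close to the preset, and its unadjusted camera p still rose from 3.2e-10 to 0.0034. These values argue against a higher correlation between genes as the cause of the loss for these lists. Their lost calls therefore cannot be read as an effect of correlated genes. The cause was not tested further. The replicate numbers showed no clear pairing of the libraries: deviations of same-numbered libraries correlated at 0.15, −0.12 and 0.16. Not every library correlated best with its own number. These few correlations cannot exclude a pairing. With the number as a replicate block 11697 genes were called, 11252 of them shared with the fit without it, and the immediate early list was not called (camera adjusted p = 0.068). No called result reversed. For named genes, called or not, 2123 results kept their direction and their side of the threshold under an alternative. For these genes 6 calls were lost and 3 gained. For lists 342 results were counted as unchanged, 16 calls as lost and 23 as gained. The gains leave out the p53 targets and the skeletal muscle list, which fry called in the direction opposite to camera. The NRF2 list, not called, was counted as unchanged although its median changed sign without WT replicate 1. With these depths, 3 libraries a group and 200 changed genes, 12.5% of the smallest simulated changes and 98.0% of 4-fold changes were recovered. Far more genes were called in the real data, so these shares need not hold there.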

Other observations

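The tests of cycling cells, of a few strong changes and of copy number on chromosome 19, of shared constant exons and of other splits of the libraries were chosen only after the result was seen. On chromosome 19 the lower genes reach into several lists: the interferon genes Ifit2, Ifit3, Ifit3b and Ifit1, the kinesin gene Kif11 and the YAP/TEAD target Ankrd1 all lie in the 30 to 40 Mb window, whose 51 tested genes had a median log2 fold change of −1.01. Acta2 lies in the same window and rose (2.37). Loxl4, Pgam1 and Psat1, also on chromosome 19, fell as well (−3.41, −1.81 and −1.38), while Tm7sf2, on the same chromosome, rose (1.17).

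The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of these, the real split, gave 11330 called genes, while the highest of the others gave 0. These splits are too few for a share under 0.05.

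Replication and mitosis genes fell together in KO, though camera did not call either list with an estimated correlation (camera adjusted p = 0.071 for both). The medians were −1.25 for replication and −1.08 for mitosis, and their highest values under 3 other scalings were −1.18 and −1.005. The fall thus does not depend on which of these scalings is used. These scalings moved list medians by at most 0.08, too little to bring either near 0. The test therefore cannot exclude an effect of scaling between libraries. Genes matched on expression, length and GC content had a typical median of −0.15 in 10000 draws for both lists, which speaks against a general trend, and a lowest of −0.66 for replication and −0.81 for mitosis; the last lies within the margin of 0.3 set beforehand for all draws, so by that rule the trend stays open for mitosis. Fewer cycling cells in KO at harvest stay open: 93.8% of the G2/M list fell with 100% of the replication list, but this is the pattern itself and could only have excluded them. Mki67 (0.01) did not fall, no cell cycle measure was used here, and a direct effect of LAP2alpha stays open as well.

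Chromosome 19 genes were mostly lower, though camera did not call the chromosome with an estimated correlation (camera adjusted p = 0.226). A few strong changes are not the whole of it: 58.8% of its 517 tested genes were called lower (lower limit of the 95% binomial interval 54.4%, with genes taken as independent), against at most 46.2% on another autosome; this test replaced an earlier one on genes changed less than 2-fold, whose filter used the change itself. Genes of other autosomes matched on GC content, density and expression had a lowest median of −0.0961 in 1000 draws, against −0.48 for the chromosome. A copy number that differs between the lines cannot be told apart from regulation: the window medians reached up to −0.181, and genes of low, middle and high expression had medians of −0.16, −0.58 and −0.62, which neither meets nor excludes a uniform loss. DNA of these lines was not analysed here.

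Protocadherin genes rose on chromosome 18, where 237 of 412 tested genes were higher and 82 lower, but with an estimated correlation camera called neither the clusters (camera adjusted p = 0.071) nor the chromosome (camera adjusted p = 0.226). A higher copy number of the chromosome would be too small. The clusters' median lay 2.03 (log2, lower limit of the 95% bootstrap interval 1.39) above that of 85 tested genes within 5 Mb. Reads shared through constant exons cannot account for the beta cluster, whose genes lack such exons and had a median of 3.06 (lower limit 2.66). Both limits take neighbouring genes as independent. A candidate explanation is lower expression of Smchd1, known to repress these clusters and picked outside the naming rule once the protocadherin pattern was seen, which fell from 154 ± 9.50 to 102 ± 8.96 CPM (log2 fold change −0.67, edgeR adjusted p = 1.1e-05; n = 3). In all, 5652 of 15081 tested genes were called lower, so the call of Smchd1 alone is weak support. Its change was also under the median absolute log2 fold change of called genes (0.78). Whether the drop in Smchd1 suffices was not tested, and an effect of LAP2alpha itself stays open.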
